A study of Mus musculus with 2 samples.

How the data were processed

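Spleens were disrupted mechanically, red cells were lysed, and libraries were built with the 10x Genomics 3' v3.1 chemistry with a target of 10000 cells per sample, per the labels' protocols. The series holds 1 wild-type library and 1 M694I knock-in library; how many mice went into each is not given beyond titles that name 1 mouse, and both groups are age-matched per the series' design text. The deposited matrices hold raw UMI counts per gene and cell barcode, with no normalization, made with Cell Ranger 6.1.2 per the file headers. The submitters' processing notes name Cell Ranger 7.1.0, Seurat 5.0.3 and the genome mm10, so the version that made the counts differs between these sources. Which gene annotation was used and how barcodes were chosen are not given in the sources used here. The knock-in file held exactly 9000 barcodes and the wild-type file 10449, each with at least 500 UMIs, and 27 barcode sequences occurred in both libraries.

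Of the 32285 features, 32158 (99.6%) were matched by Ensembl ID to the GENCODE M21 annotation of GRCm38, which is mm10, and gene positions, transcript lengths and GC content came from it. Cells with at least 500 UMIs, at least 200 genes and under 10% mitochondrial UMIs were kept: 48 wild-type and 21 knock-in barcodes missed the first limits, and 668 (6.39%) and 396 (4.40%) had 10% mitochondrial UMIs or more. Doublets were called in each library with Scrublet in scanpy 1.11.5 (expected rate 0.08), which marked 222 wild-type cells (2.28%) and 174 knock-in cells (2.03%), and were removed. The kept cells held 30174536 and 23897399 UMIs.

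Both libraries were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen after leaving out immunoglobulin and T cell receptor segments, sex-linked, haemoglobin, ribosomal protein and mitochondrial genes and the type I interferon, interferon gamma and stress lists. Then 30 principal components, 15 exact nearest neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1) gave 22 clusters. Clusters were named from marker lists fixed before the data were examined. The scoring was set after the clusters had been seen: each marker's level was placed between its lowest and highest cluster, a cluster took the list with the highest mean, and at least 3 of its markers had to be detected in 10% of cells. Clusters with at least 5 cell cycle genes among their 10 leading genes stayed unnamed. The lists for conventional and plasmacytoid dendritic cells were joined after a cluster had been seen to hold both. Sub-classes needed a mean of at least 0.7, a threshold also set after the data had been seen, which left 70.6% of wild-type and 74.6% of knock-in B-like cells and 0% of T-like cells without a sub-class. A germinal centre sub-list named no cluster.

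UMIs were summed per library and class, divided by the class total and scaled to CPM, and compared as log2 ratios of knock-in over wild-type, in classes of at least 100 cells per library. Sums carry exact Poisson intervals, shares exact Clopper-Pearson intervals and ratios exact conditional binomial intervals, all at 95% and for counting error only. A library at 0 UMIs was placed at a floor of 3 counts. A list's median was taken over members with a mean CPM of at least 10 and at least 20 UMIs summed over both libraries, members were called higher or lower at a log2 ratio of 0.32 in size, and the median's percentile was taken among 10000 random lists of the same size matched on mean expression in 20 bins. No significance test was made, because cells are not replicates of a genotype.

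Genes were named by a rule of size. In all kept cells and in each class of at least 500 cells per library, the 5 highest and 5 lowest log2 ratios were taken among genes with a mean CPM of at least 50 and at least 100 UMIs. This left out antigen receptor segments, sex-linked, haemoglobin, ribosomal protein and mitochondrial genes (given as groups) and symbols that are only clone or model names. Each list added its 4 members with the largest absolute ratios over all kept cells, and its 3 largest in any class where its median lay outside the central 95% of random lists; the text names a part of these. Malat1 and Neat1 were chosen after their values had been seen. The lists covered type I interferon, interferon gamma, MHC class I and II, inflammasome, NF-kB and TNF, IL-1, IL-6 and neutrophil activation, stress, cytotoxic, T cell activation, naive T cell, B cell activation, cell cycle, oxidative phosphorylation, haemoglobin, sex-linked, ribosomal protein and mitochondrial genes.

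The samples, the lists, the naming rule for genes, the filters and the alternatives listed next were fixed before the data were examined. These were a 5% mitochondrial limit, at least 1000 UMIs and 500 genes per cell, doublets kept, Leiden resolution 2, all variable genes, each library clustered alone, TMM factors (edgeR 4.0.16, R 4.3.3), a total without immunoglobulin, haemoglobin, ribosomal protein and mitochondrial genes, cells thinned to 1000 UMIs, cells weighted equally, other expression filters for lists, the mean over members, lists without their largest member and classes weighted to their mean shares. Leaving out cells with a Cd79a UMI, or with over 20 Jchain or over 20 haemoglobin UMIs, was added after seeing the data. Log2 ratios of the measured genes were regressed on log2 transcript length, GC content and log2 mean CPM, without and with log2 gene span, in B-like, T-like, CD4 T-like, CD8 T-like, marginal zone B-like, dendritic-like and monocyte-like cells. The median residuals of the interferon, MHC class I and NF-kB lists were compared with those of matched random lists. This regression was chosen after the list medians, but before its residuals, had been seen, and gene span was added after them. Thinning left out 157 wild-type and 379 knock-in cells.

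The steps were tested on simulated counts with 200 changed genes among those measured in each comparison. The intervals covered the true ratio for 95.4% of 7055 genes in all kept cells, 95.3% of 6834 in B-like, 95.7% of 6782 in T-like and 96.2% of 5965 in monocyte-like cells. The simulated sums were Poisson draws without cells, which is what the intervals assume. This coverage therefore checks the calculation and not whether the intervals hold for UMIs that cluster in cells. The 50 highest and 50 lowest ratios were all changed genes in the first 3 comparisons, but only 21 and 23 of 50 in monocyte-like cells. Single genes of that class are thus the least certain of the 4 comparisons simulated, and other small classes were not simulated. Of 100 unchanged lists, 6, 3, 2 and 3 fell outside the central 95% of random lists in these 4 comparisons. Numerical work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9 and matplotlib 3.10.9.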

Results

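Gene expression was measured in single spleen cells of the mouse by droplet sequencing of transcript 3' ends, with unique molecular identifiers (UMIs) that count each captured RNA molecule once. The design holds 1 library of wild-type splenocytes and 1 library of splenocytes with a knock-in of the M694I change in Mefv. Mefv codes for pyrin, an inflammasome sensor, and changes of its human counterpart underlie familial Mediterranean fever. The comparison asks how splenic immune cells differ between the genotypes, above all in interferon and inflammatory programmes. The wild-type library held 10449 barcodes with 32797052 UMIs, of which 9511 cells with a median of 2527 UMIs and 1032 genes were kept. The knock-in library held 9000 barcodes with 25193274 UMIs, of which 8409 cells with a median of 2023 UMIs and 894 genes were kept. With 1 library per genotype there was no replicate and no test: every interval below is a 95% interval that covers counting error only, and each value compares these libraries rather than the genotypes. Intervals of gene sums and ratios take UMIs as independent, so they are too narrow where few cells hold many of a gene's UMIs. Ratios are knock-in over wild-type throughout.

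Mefv (ENSMUSG00000022534) lies on chromosome 16 from 3707218 to 3718097 on the minus strand of GRCm38 (mm10), with 3 annotated protein-coding transcripts of 9 or 10 exons. The deposited counts hold no read sequence, so they do not check the edit. A change of the gene's 3' end by the knock-in could alter how this assay counts Mefv. This was not tested, so the ratios below may not be those of its expression. In all kept cells Mefv gave 144 UMIs in the wild-type and 77 in the knock-in library, or 4.77 (4.02 to 5.62) and 3.22 (2.54 to 4.03) CPM (UMIs scaled to a common total), a log2 ratio of -0.57 (-0.99 to -0.16). Its transcripts lay mainly in monocyte-like cells, with 74 and 44 UMIs (94.7 and 77.8 CPM, log2 ratio -0.28, -0.86 to 0.27), and in dendritic-like cells, with 55 and 18 UMIs (51.2 and 22.7 CPM, log2 ratio -1.17, -2.03 to -0.38). A Mefv UMI was found in 24.9% and 19.6% of monocyte-like cells, at median depths of 4236 and 2913 UMIs. Among dendritic-like cells, 16.5% (11.4% to 22.7%) and 9.76% (5.68% to 15.4%) held a Mefv UMI, at 5466 and 4483 UMIs. These intervals overlapped. In B-like cells, which should lack it, the shares were 0.0623% and 0.0729% at 2338 and 1805 UMIs. Neutrophil-like cells held 6 and 4 Mefv UMIs, and the NK-like and macrophage-like classes held 0 in both libraries. With every cell thinned to 1000 UMIs the dendritic-like ratio was -2.14, which rests on only a part of the 55 and 18 UMIs and has no interval.

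Plasma cell-like cells were a 5.14-fold larger share of the knock-in library (3.55 to 7.64), with 35 wild-type cells (0.368%) and 159 knock-in cells (1.89%). Neutrophil-like cells were 1.89-fold lower in the knock-in library (1.37 to 2.64), with 122 cells (1.28%) and 57 cells (0.678%). Their median depths, 1080.5 and 1086 UMIs, were the lowest of the classes. This share may therefore depend on how barcodes were chosen before deposit, which is not given and was not tested. NK-like cells were 1.41-fold lower (1.20 to 1.65), at 4.41% and 3.13%. B-like cells made up 67.5% and 65.2% and T-like cells 21.02% and 22.5%. Within the B-like class, cluster 3, with Mir155hg, Nfkbid and Irf4 among its leading genes, held 1387 wild-type and 443 knock-in cells. Cluster 1, with Bcl11a and Fcer2a among its leading genes, held 879 and 1468. Within the T-like class the sub-classes differed in opposite directions. CD4 T-like cells were 1.69-fold lower in the knock-in library (9.77% and 5.79%), CD8 T-like cells 1.51-fold higher (7.50% and 11.3%) and regulatory T-like cells 1.55-fold higher (3.34% and 5.18%). The lower CD4 T-like share lay in cluster 5, with 714 wild-type and 240 knock-in cells, and not in cluster 11, with 215 and 247. Clustering was without batch integration, and whether cells shifted between clusters for that reason was not tested. Foxp3, the lineage factor of regulatory T cells, gave a UMI in 5.97% and 6.19% of regulatory T-like cells (median depths 2857 and 2130 UMIs), against 0 of 6418 and 1 of 5484 B-like cells. Foxp3 was thus not detected in most cells of the regulatory T-like class, and how many of them were regulatory T cells cannot be told. Cd4, Icos and Izumo1r were among the leading genes of the regulatory T-like class. The lower CD4 T-like share is therefore not that of all Cd4-expressing T cells, since the regulatory T-like share was higher. Marginal zone B-like cells were 6.70% and 4.94%, and immature or transitional B-like cells 13.1% and 11.6%. Monocyte-like cells were 1.95% and 2.13%, dendritic-like cells 1.91% and 1.95%, macrophage-like cells 0.736% and 0.868%, and gamma-delta T-like cells 0.410% and 0.274%. A proliferating cluster left unnamed held 0.852% and 1.61%.

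Some of these shares depended on the cells kept. A mitochondrial limit of 5%, which kept 5549 wild-type cells, turned the log2 ratio of B-like cells from -0.05 to 0.10, of T-like cells from 0.10 to -0.18, of dendritic-like cells from 0.03 to -0.29, of monocyte-like cells from 0.13 to -0.11, of marginal zone B-like cells from -0.44 to 0.28 and of immature or transitional B-like cells from -0.17 to 0.04. With each library clustered alone, the plasma cell-like and macrophage-like classes could not be named in the wild-type library, and the dendritic-like log2 ratio was -1.96.

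**Figure D1:**
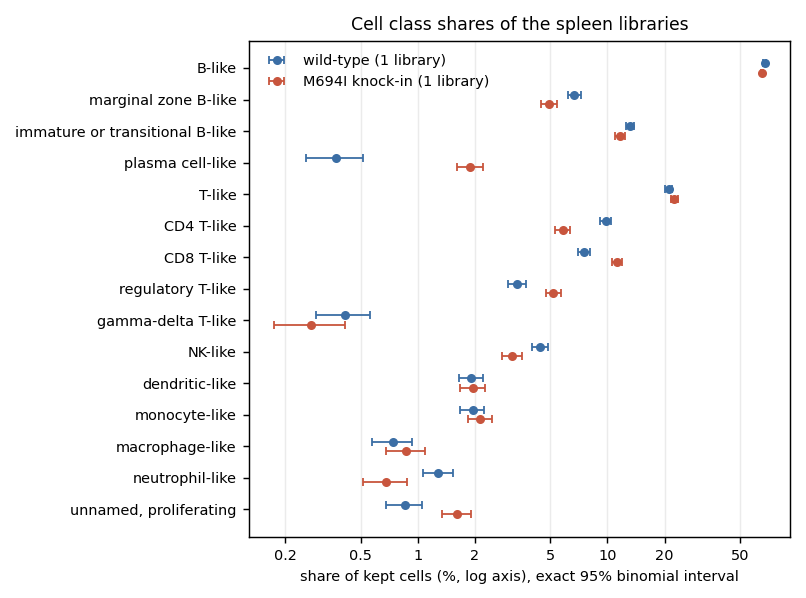
Share of kept cells in each class (percent, log axis) in the wild-type library (blue) and the knock-in library (red); bars are exact 95% binomial intervals and cover counting error only. The plasma cell-like share was 0.368% in the wild-type and 1.89% in the knock-in library.

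Over all kept cells, immunoglobulin and neutrophil granule transcripts led the genes that were higher in the knock-in library. Ighg2b, the constant region of an IgG heavy chain, was at 7.03 CPM in the wild-type and 525 CPM in the knock-in library (log2 ratio 6.22, 6.03 to 6.43). Plasma cell-like cells held 48 wild-type and 11884 knock-in UMIs of it, and it was the leading heavy chain gene in 0 of 35 and 11 of 159 of them. Its interval does not cover the sampling of so few cells. Jchain, which joins IgM and IgA into polymers, was at 533 and 3411 CPM (2.68, 2.65 to 2.70). Iglc1, a lambda light chain constant region, had a log2 ratio of 2.51, but 1 knock-in cell held 51.8% of its knock-in UMIs and the ratio was 1.59 without the highest cell of each library. The granule genes Ngp and Camp had log2 ratios of 3.29 and 3.05, and 1 wild-type cell held 95.6% and 91.0% of their wild-type UMIs. Without the highest cell of each library these ratios were 7.32 and 6.17. The 5 genes with the lowest ratios were Cd200, a membrane glycoprotein that restrains myeloid cells (-0.95), Dip2b (-0.87), Ddx21, an RNA helicase of the nucleolus (-0.85), the non-coding Dleu2 (-0.84) and Nr4a3, an orphan nuclear receptor induced by antigen receptor signals (-0.83, and -0.55 with cells thinned to 1000 UMIs).

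The list of B cell activation and differentiation genes was higher over all kept cells, with a median log2 ratio of 0.45 at percentile 100 among 10000 random gene lists of the same size matched on mean expression. Percentiles of this kind describe these libraries only. Of its 16 measured members, 10 were higher by a log2 ratio of at least 0.32 and 2 lower by as much, the limit used for list members throughout. Besides Ighg2b and Jchain, Ighg3 had a log2 ratio of 1.26 (1.22 to 1.30), with 49.3% of its wild-type UMIs in 1 cell and 1.88 without the highest cells, and Ighg1 one of 3.80, with 93.4% of its knock-in UMIs in 1 cell and 0.36 without the highest cells. With classes weighted to their mean shares the list's median was -0.02, and within the B-like class it was 0.18, at percentile 93.0. In monocyte-like cells it was -0.38 (percentile 1.83), and 0.04 with cells thinned to 1000 UMIs.

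The type I interferon list had a higher median in knock-in T-like and B-like cells, and the interferon gamma list in T-like cells. In T-like cells the type I interferon list had a median log2 ratio of 0.30 (0.19 to 0.39, percentile 100), with 14 of 30 measured members higher and 2 lower, and 0.19 with no expression filter. Irf7, a transcription factor that amplifies type I interferon, was at 30.4 CPM in wild-type and 63.3 CPM in knock-in T-like cells (1.06, 0.81 to 1.31). Ifit3, an interferon-induced antiviral protein, had a log2 ratio of 0.99 (0.54 to 1.46), and Isg20, an interferon-induced exonuclease, one of 0.79 (0.36 to 1.22). The interferon gamma list in T-like cells had a median of 0.39 (0.25 to 0.44, percentile 100), with 15 of 27 members higher and 1 lower. After regression on transcript length, GC content and expression level it was 0.26 (percentile 100). Psmb8, a catalytic subunit of the immunoproteasome, was at 209 and 397 CPM (0.92, 0.83 to 1.02) and the proteasome activator Psme2 at 197 and 317 CPM (0.68, 0.58 to 0.78). The chemokine Cxcl10 went the other way (-0.81, -1.13 to -0.49), and was at -0.38 with each cell weighted equally.

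By T-like sub-class, the type I interferon median was 0.56 in CD4 T-like cells (0.31 to 0.66, percentile 100, 18 of 28 members higher and 3 lower), 0.17 in CD8 T-like cells (0.10 to 0.32, percentile 97.8, and 0.27 with cells thinned to 1000 UMIs) and 0.07 in regulatory T-like cells (percentile 78.3). The CD4 T-like class joined cluster 5, with 714 wild-type and 240 knock-in cells, and cluster 11, with 215 and 247 cells. The type I medians within these clusters were 0.29 (percentile 97.1, inside the random range) and 0.34 (98.2), and the interferon gamma medians 0.47 (99.99) and 0.18 (-0.02 to 0.42, percentile 76.5, inside the random range). Ly6a (Sca-1), an interferon-inducible surface protein, had log2 ratios of 1.03 in CD4 T-like and 1.70 in CD8 T-like cells. Ifi208 had one of 1.12 in CD4 T-like cells, and Oasl2 one of -0.98 in CD8 T-like cells. Stat2, a transducer of type I interferon signals, was at 1.10 in CD4 T-like cells and at -0.26 with cells thinned to 1000 UMIs. The interferon gamma medians were 0.50 in CD4 T-like cells (20 of 26 members higher) and 0.28 in CD8 T-like cells (11 of 26 higher), at percentiles 100 and 99.95. In CD4 T-like cells scaling by TMM factors shifted all log2 ratios by -0.13, which left type I interferon at 0.43.

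In B-like cells the type I interferon median was 0.18 (0.12 to 0.24, percentile 99.3), with 7 of 22 members higher and 1 lower, and 0.11 at the 5% mitochondrial limit. The cells of this class lay mainly in clusters 0, 3 and 2 in the wild-type library and in clusters 0, 1 and 2 in the knock-in library. No medians were taken within clusters 0, 1 and 3, so the B-like values may also carry this difference in mix. Ly6a, at 133 and 236 CPM (0.83, 0.75 to 0.91), Zbp1, a sensor of unusual nucleic acids (0.50), and Isg20 (0.45) were the members with the largest differences; Zbp1 was at 0.82 with cells thinned to 1000 UMIs and 0.32 at the 5% mitochondrial limit. In marginal zone B-like cells 11 of 21 members were higher and 0 lower, with a median of 0.40 (0.20 to 0.54, percentile 100), 0.25 with doublets kept and 0.00 with cells thinned to 1000 UMIs. Ifit3 had a log2 ratio of 2.51 there, from 17 and 56 UMIs. Immature or transitional B-like cells had a median of 0.14 (percentile 94.9). The interferon gamma medians were 0.13 in B-like cells (percentile 97.2, inside the central 95% of random lists) and 0.18 in marginal zone B-like cells (percentile 99.2), the latter 0.52 with cells thinned to 1000 UMIs and 0.33 at the 5% mitochondrial limit.

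**Figure D2:**
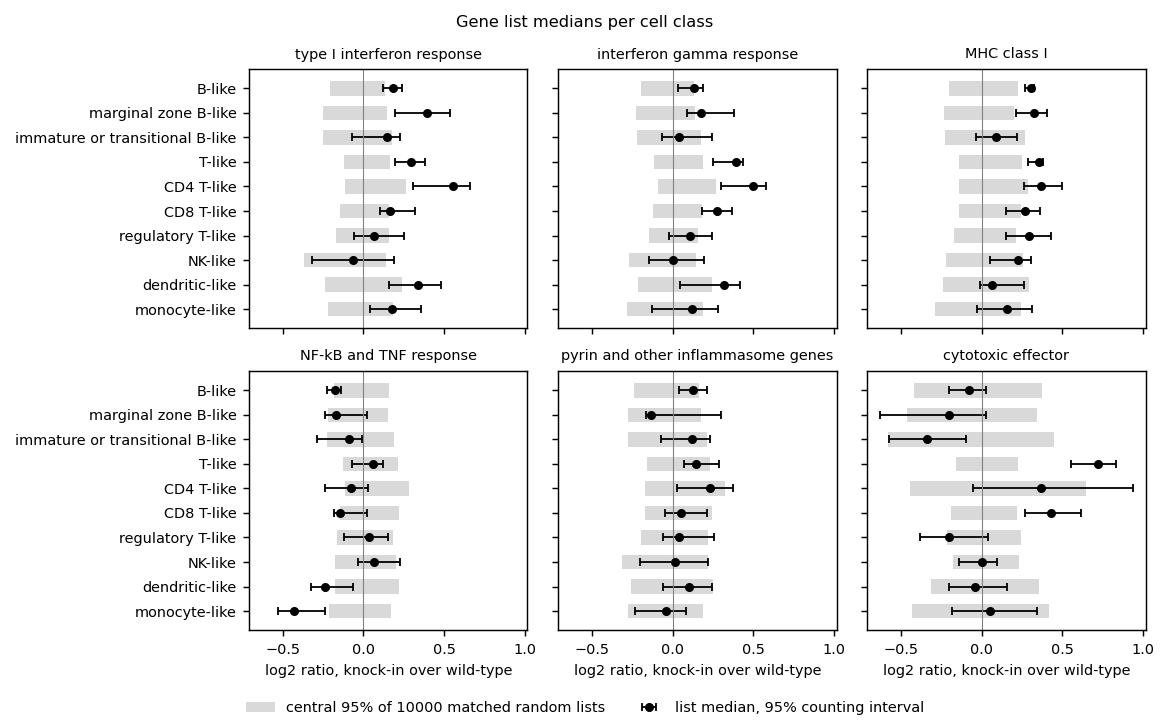
Median log2 ratio (knock-in over wild-type) of 6 gene lists in 10 cell classes. Points are list medians with 95% counting intervals, and grey bars span the central 95% of 10000 matched random lists; the type I interferon median was 0.56 in CD4 T-like and -0.06 in NK-like cells.

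In dendritic-like cells the type I interferon list had a median of 0.34 (0.16 to 0.48, percentile 99.7) and the interferon gamma list one of 0.32 (percentile 99.7). B cell transcripts (Cd79a, Cd79b or Ms4a1) were present in 53 of 182 and 41 of 164 of these cells, and without the cells that held a Cd79a UMI the medians were 0.15 and 0.14. The type I median there was 0.13 at the 5% mitochondrial limit and 0.66 with cells thinned to 1000 UMIs, and the gamma median was 0.18 after regression on transcript length, GC content and expression level (percentile 95.3), inside the random range. Monocyte-like cells had a type I interferon median of 0.18 (percentile 97.2) and NK-like cells one of -0.06 (percentile 70.2), both inside the random range. After that regression the monocyte-like median was 0.27 (percentile 99.6), outside it. Over all kept cells together the type I and gamma lists stood at 0.06 (percentile 95.5) and 0.08 (percentile 95.4). Isg20 (1.17), Ly6a (1.07), Zbp1 (0.63) and Bst2, which tethers budding virus (0.56), were the type I members with the largest differences there, Isg20 at 0.71 both with cells thinned to 1000 UMIs and with cells weighted equally. In the gamma list these were Psmb8 (0.86), Psmb9 (0.75) and Psmb10 (0.57) on the higher side and Ciita, the activator of MHC class II genes, on the lower (-0.69).

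MHC class I genes were higher in most lymphoid classes. The list's median was 0.31 in B-like (percentile 99.7), 0.36 in T-like (99.9), 0.37 in CD4 T-like (99.6), 0.27 in CD8 T-like (98.6), 0.29 in regulatory T-like (99.7) and 0.33 in marginal zone B-like cells (99.9). Within single clusters it lay inside the random range in both CD4 T-like ones (0.31 at percentile 97.2 in cluster 5 and 0.29 at 96.8 in cluster 11) and both CD8 T-like ones (0.27 at 96.3 in cluster 6 and 0.17 at 85.2 in cluster 8). It was 0.23 over all kept cells (98.5). No measured member was lower in any of these by the limit for members. The non-classical molecules H2-T23 and H2-T22 led the list, at 218 and 337 CPM (0.63) and at 62.6 and 100.1 CPM (0.68) in B-like cells. The peptide transporter subunit Tap2 had a log2 ratio of 0.52 in B-like cells, and H2-M3, which presents formylated peptides, one of 0.59 in T-like cells. Scaling by TMM factors put the CD4 T-like median at 0.24, and the 5% mitochondrial limit put the CD8 T-like median at 0.18. After regression on transcript length, GC content and expression level the medians were 0.20 in B-like (percentile 97.6, and 0.18 at 96.9, inside the random range, with gene span added), 0.20 in T-like (98.2) and 0.14 in CD8 T-like cells (92.5), the last inside the random range too. NK-like cells (0.23), immature or transitional B-like cells (0.09), monocyte-like cells (0.16) and dendritic-like cells (0.06) lay inside the random range.

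**Figure D3:**
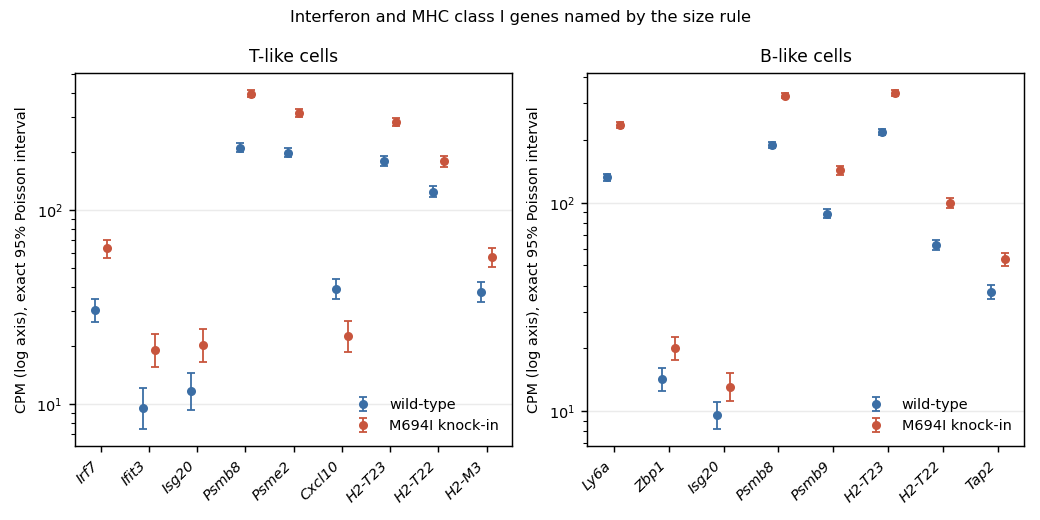
CPM (log axis) of the interferon and MHC class I list members named by the size rule in T-like cells (left) and B-like cells (right), wild-type in blue and knock-in in red, with exact 95% Poisson intervals. Psmb8 was at 209 and 397 CPM in T-like cells, and Cxcl10 is the single gene drawn that was lower in the knock-in library.

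Cytotoxic genes were higher in knock-in T-like cells, with a median of 0.72 (0.56 to 0.83, percentile 100), 12 of 16 measured members higher and 1 lower. The granule protein Nkg7 was at 156 and 334 CPM (1.10, 0.99 to 1.21), and the chemokine Ccl5 at 1692 and 3454 CPM (1.03, 1.00 to 1.06). The granzymes Gzmk and Gzmm had log2 ratios of 2.22 (27 and 96 UMIs) and 1.27. Gzma, another granzyme, had one of -1.87, but 1 cell held 51.2% of its wild-type UMIs and the ratio was 0.40 at the finer clustering. Ctsw (1.00) and Cd8a (0.96), both markers of CD8 T cells, and Gimap7, a lymphocyte GTPase (0.94), completed the 5 genes with the highest ratios. CD8 T-like cells made up 35.7% of wild-type and 50.1% of knock-in T-like cells. Within CD8 T-like cells the cytotoxic median was 0.43 (0.27 to 0.61, percentile 100), with 8 of 16 members higher and 1 lower. This class joined cluster 6, with 428 wild-type and 510 knock-in cells, and cluster 8, with 285 and 439 cells. The cytotoxic medians within them were 0.28 (-0.22 to 0.46, 7 members, percentile 90.5), inside the random range, and 0.41 (0.26 to 0.62, percentile 99.99). Gzmk (2.07), Gzmb (1.27) and Gzmm (1.04) led the list in the class, the first 2 at 1.24 and 2.14 with cells thinned to 1000 UMIs. The T cell activation and checkpoint list had a median of 0.36 in T-like cells (percentile 99.9), with the inhibitory receptors Lag3 (1.33) and Pdcd1 (1.22) higher and Cd40lg, a helper ligand of CD4 T cells, lower (-0.79). It stayed inside the random range in CD4, CD8 and regulatory T-like cells, at -0.04, 0.09 and 0.14. The naive T cell list lay inside the random range in every class, at 0.06 in T-like cells.

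The genes with the lowest ratios in T-like cells were Dip2b (-0.95), Dgat1, an enzyme of triglyceride synthesis (-0.89), Mast4 (-0.84), Stat5a, a transducer of cytokine signals (-0.84), and Aff1 (-0.81). In CD8 T-like cells Igfbp4 (1.15), Gimap7 (1.00), Psmb8 (0.96), Plaat3 (0.94) and Etfb (0.91) had the highest ratios. H2-Aa (-1.05), Dip2b (-1.03), H2-Ab1 (-1.01), Dleu2 (-0.98) and H2-Eb1 (-0.97) had the lowest. With doublets kept H2-Ab1 and H2-Eb1 were at -0.54 and -0.53 there, and Plaat3 was at 0.52 with cells thinned to 1000 UMIs. In regulatory T-like cells the cell cycle list was lower, with a median of -0.37 (percentile 0.010), 13 of 22 members lower and 1 higher, and -0.22 in cells thinned to 1000 UMIs.

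In B-like cells the immediate early factor Fos was at 207 and 376 CPM (0.86, 0.80 to 0.92), and Ly6a, Psmb8 (0.78), Psmb9 (0.69) and the peroxiredoxin Prdx2 (0.68) followed. Susd6 (-0.85), Cd200 (-0.84), Ddx21 (-0.82), Brd9, a bromodomain protein (-0.79), and Slc7a1, a transporter of cationic amino acids (-0.79), had the lowest ratios. B-like values are over a mix of clusters that differed between the libraries, as given above. In immature or transitional B-like cells Stmn1 (0.94), Rnf187 (0.90), Gadd45a, a stress-induced growth arrest gene (0.90), Ly6a (0.89) and Mzb1, a chaperone of immunoglobulin assembly (0.87), were highest. Brd9 (-1.44), Mob1a (-1.12), the immediate early factor Egr1 (-1.05), Nudcd3 (-1.01) and Dleu2 (-0.97) were lowest there. The activation and checkpoint list was lower in B-like (-0.33, percentile 1.38) and marginal zone B-like cells (-0.54, percentile 0.080), with Nr4a3 at -0.75 and -1.06 and Nr4a2 at -0.46 and -0.58, the latter -0.31 with cells weighted equally. With no expression filter these medians were -0.18 and -0.13. In dendritic-like cells the list's median was -0.36 (percentile 1.28), and between -0.75 and -0.26 under the alternatives.

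Genes of the pyrin and other inflammasomes stood inside the range of random lists in every class. Their median was 0.03 over all kept cells (percentile 83.4), with 3 of 16 members higher and 3 lower, -0.04 in monocyte-like (percentile 47.9) and 0.10 in dendritic-like cells (percentile 75.9). Pycard, the adaptor that links pyrin to caspase-1, was at 51.8 and 88.6 CPM over all kept cells (0.77, 0.68 to 0.87), and Casp1 at 16.9 and 26.1 CPM (0.63, 0.46 to 0.80). The cytokine Il1b was at 35.7 and 19.8 CPM (-0.85, -1.01 to -0.69), and Gsdme, a pore-forming gasdermin, had a log2 ratio of -0.35 (-0.60 to -0.11), and -0.14 with cells thinned to 1000 UMIs. The neutrophil-like class, whose leading genes include Il1b and Cxcl2, was the smaller share in the knock-in library given above.

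NF-kB and TNF response genes were lower in knock-in monocyte-like and dendritic-like cells. The median was -0.43 in monocyte-like cells (-0.53 to -0.24, percentile 0.010), with 14 of 25 members lower and 2 higher, and -0.24 in dendritic-like cells (-0.32 to -0.06, percentile 0.54), with 10 of 26 lower and 3 higher, and -0.12 there at the 5% mitochondrial limit. The monocyte-like class joined cluster 13 (122 wild-type and 102 knock-in cells) and cluster 19 (63 and 77). The dendritic-like class joined cluster 12 (146 and 132) and cluster 20 (36 and 32). Medians within these clusters were not taken, so a difference in mix may contribute. The neutrophil transcripts S100a8 and S100a9 were lower in both classes too, with 277 wild-type UMIs in 12 and 112 knock-in UMIs in 3 monocyte-like cells (log2 ratio of the sums -0.84, -1.17 to -0.52), and 351 and 2 UMIs in dendritic-like cells. That interval takes UMIs as independent and does not cover the sampling of so few cells. In monocyte-like cells the growth factor Csf1 had a log2 ratio of -1.85 (-3.41 to -0.57), and -1.10 with cells weighted equally. Ccl4, a chemokine, had one of -2.17, but 1 wild-type cell held 77.9% of its UMIs and the ratio was -0.54 without the highest cells. In dendritic-like cells Ccl3 (-2.60) and Ccl4 (-1.60) were lower and the antioxidant enzyme Sod2 was higher (0.96). Over all kept cells the median was -0.25 (percentile 0.83, 9 of 24 members lower and 0 higher), led by Tnfaip2 (-1.09), the neutrophil chemokine Cxcl2 (-0.96) and the NF-kB subunit genes Nfkb2 (-0.66) and Nfkb1 (-0.46). It was -0.14 with classes weighted to their mean shares. The median of B-like cells, -0.18, lay inside the random range; it was -0.17 (percentile 0.53), outside that range, after regression on transcript length, GC content and expression level.

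The list of IL-1, IL-6 and neutrophil activation genes had a median of -0.34 over all kept cells (percentile 0.26, 7 of 14 members lower and 4 higher), but its members went apart. The iron-binding Lcn2 had a log2 ratio of 2.84, with 62.7% of its wild-type UMIs in 1 cell, and one of 3.95 without the highest cells and 1.69 with cells weighted equally, and the lectin receptor Clec4d one of -1.33. S100a8 and S100a9 were both at 1.15, and at 0.02 and -0.03 with cells thinned to 1000 UMIs. The mean over members was 0.08. In B-like cells the median was -0.35 (percentile 0.30) and 0.00 with the higher expression filter. In dendritic-like cells it was -0.35 (percentile 0.33), where S100a8 and S100a9 gave 351 wild-type UMIs, 227 of them in 1 cell, and 2 knock-in UMIs; the median was -0.15 with cells thinned to 1000 UMIs. In regulatory T-like cells it was 0.30 (percentile 98.4), and 0.08 with no expression filter.

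MHC class II genes differed mainly in classes that do not make them. Their median was 1.60 in NK-like, 1.53 in regulatory T-like and 0.51 in CD4 T-like cells (percentiles 100, 100 and 99.7). The summed B cell transcripts Cd79a, Cd79b and Ms4a1 were also higher in NK-like and regulatory T-like cells, with log2 ratios of 2.18 and 1.07. In CD4 T-like cells theirs was 0.14 (-0.12 to 0.40), within counting error, and 8.93% and 6.78% of these cells held one of them. Without cells that held a Cd79a UMI the MHC class II medians were 0.00, 0.21 and 0.23. In NK-like cells the median was 0.57 with doublets kept. In CD8 T-like cells the median was -0.65 (percentile 0), and -0.28 with doublets kept. There 10.2% of wild-type and 6.74% of knock-in cells held one of the B cell transcripts, whose summed log2 ratio was -0.12 (-0.45 to 0.20). The list lay inside the random range in B-like cells (0.14), dendritic-like cells (0.08) and over all kept cells (-0.02).

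Immediate early and dissociation stress genes were higher in knock-in lymphocytes, with medians of 0.26 in B-like (percentile 99.6), 0.36 in NK-like (100, and 0.23 with doublets kept), 0.44 in CD4 T-like (100), 0.27 in CD8 T-like (99.7) and 0.31 in regulatory T-like cells (100), the last 0.13 in cells thinned to 1000 UMIs. Jun, at 147 and 350.4 CPM, and Atf3 (1.08, and 0.55 at the 5% mitochondrial limit) led in CD4 T-like cells. The classes with higher interferon lists thus included 3 with a higher stress list, B-like, CD4 T-like and CD8 T-like. The T-like class as a whole had a stress median of 0.19 (0.17 to 0.29, percentile 93.0), and marginal zone B-like and dendritic-like cells had medians of 0.10 and -0.05, all inside the random range. Over all kept cells Hspa1a, a heat shock chaperone, had a log2 ratio of 1.33, with 42.0% of its knock-in UMIs in 1 cell, and was at 0.93 without the highest cells, 0.61 with cells weighted equally and 0.36 at the 5% mitochondrial limit. The cell cycle list was higher over all kept cells (0.46, percentile 100, 11 of 18 members higher and 0 lower), led by Cenpf (1.39), Mki67 (1.38) and Birc5 (1.38), and was at 0.23 with classes weighted to their mean shares and 0.15 in cells thinned to 1000 UMIs. In dendritic-like cells it was 0.46 (percentile 99.9), and -0.10 in cells thinned to 1000 UMIs.

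Mitochondrially encoded transcripts were lower in the knock-in library, with a median of -0.41 over all kept cells (percentile 0, 8 of 13 lower and 0 higher), -0.37 in B-like and -0.17 in T-like cells. The median share of mitochondrial UMIs per cell was 4.68% and 3.99%. At the 5% mitochondrial limit the medians over all kept and in B-like cells were -0.25 and -0.20. mt-Nd3 was the member with the largest difference, at 529 and 205 CPM (-1.37). Nuclear genes of oxidative phosphorylation stood at 0.07 over all kept cells (percentile 57.1), inside the random range, and at -0.09 in regulatory T-like cells (percentile 1.09). Ribosomal protein genes had a median of -0.03 over all kept cells (percentile 3.11), with 19 of 80 members lower and 0 higher, Rps29 (-0.79), Rps21 (-0.70), Rps28 (-0.68) and Rps15 (-0.67) among them. In T-like cells their median was -0.07 (percentile 0.030), and -0.13 with TMM factors. Y-linked genes summed to 263 and 250 CPM and Xist to 4 and 2 UMIs, and the sex-linked list lay inside the random range in every class.

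Haemoglobin transcripts summed to 129 and 1848 CPM over all kept cells, after a lysis of red cells in both preparations. Cells with over 50 haemoglobin UMIs, 5 wild-type and 20 knock-in, held 86.4% and 98.0% of them. The list's medians of 1.34 in B-like, -3.96 in T-like, -5.37 in CD4 T-like, -3.10 in marginal zone B-like and 6.65 in immature or transitional B-like cells each rested on 3 or fewer such cells per library, and no median could be formed without cells of over 20 haemoglobin UMIs.

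Across genes, longer transcripts were lower in the knock-in library. Spearman's rho of the log2 ratio with transcript length, over genes other than ribosomal protein and mitochondrial ones, was -0.45 in B-like cells (6739 genes), -0.36 in T-like, -0.29 in dendritic-like, -0.25 in NK-like and -0.23 in monocyte-like cells; genes are not independent replicates. In B-like cells the median log2 ratio was 0.12 in the shortest and -0.24 in the longest of 4 bins of transcript length with equal numbers of genes. The nuclear non-coding RNAs Malat1 and Neat1 were lower too, with log2 ratios of -0.63 and -0.40 in B-like and -0.53 and -0.20 in T-like cells. Of the genes with low ratios named above, Dip2b (6617 nucleotides) went from -0.95 to -0.76 in T-like cells after regression on transcript length, gene span, GC content and expression level, and Aff1 (8312 nucleotides) from -0.81 to -0.58. Over all kept cells Dip2b went from -0.87 to -0.50. Among short interferon genes, Psmb8 (840 nucleotides) went from 0.78 to 0.61 in B-like cells.

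**Figure D4:**
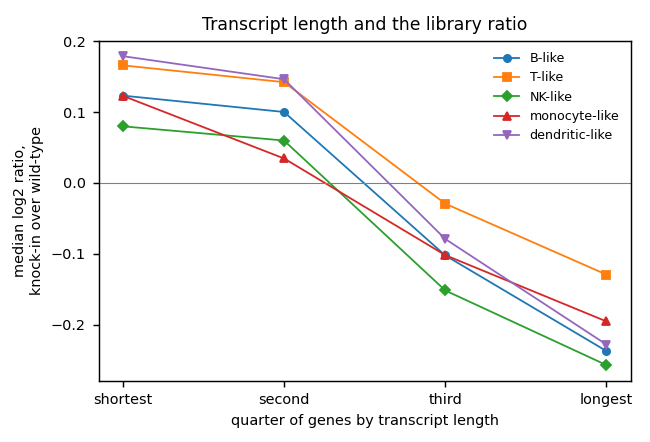
Median log2 ratio (knock-in over wild-type) of genes in 4 bins of transcript length with equal numbers of genes, 1 line per cell class, without ribosomal protein and mitochondrial genes. In B-like cells the median was 0.12 for the shortest and -0.24 for the longest bin.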

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

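Leaving out cells with a Cd79a UMI, or with over 20 Jchain or haemoglobin UMIs, were tests chosen only after the results had been seen; the other alternatives were set beforehand. No paired analysis was possible because each genotype has 1 library and the results come from no test. Of 80 class shares under the alternatives, 70 kept their sign. By size, 67 lay within the interval of the value reported, 9 moved beyond it, and 4 changed sign where that interval excluded equal shares. Of 172 medians for the interferon, inflammasome and NF-kB lists in all kept, B-like, T-like and monocyte-like cells, 167 kept their sign, and 147 stayed within their intervals and 25 moved. Of 1861 other list medians 1689 kept their sign, and 9 changed it for a list that lay outside the random range. Of 1948 values of named genes 1928 kept their sign, and 16 changed it where the reported interval excluded 0. The plasma cell-like log2 ratio of shares lay between 2.09 and 2.49 in the 5 alternatives that gave one. For each value below that moved or changed direction, the cause was not tested.

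At the 5% mitochondrial limit the log2 ratios of shares were 0.10 for B-like (-0.05 otherwise), -0.75 for NK-like, -0.18 for T-like, -0.29 for dendritic-like, -1.17 for CD4 T-like, 0.40 for CD8 T-like, 0.037 for immature or transitional B-like and 0.28 for marginal zone B-like cells. That limit kept 5549 wild-type cells with medians of 2600.0 UMIs and 1053 genes, and knock-in medians were 2129 UMIs and 923 genes. The type I interferon median was -0.0080 in all kept cells and 0.11 in B-like cells, the interferon gamma median 0.022 in all kept cells, and the NF-kB median -0.35 in all kept and -0.26 in B-like cells. H2-Eb1 in all kept cells was at 0.0053, Egr1 in CD8 T-like cells at 0.082, and Hba-a2, Hba-a1 and Hbb-bs in marginal zone B-like cells at 0.11, 0.69 and 0.86, against -3.36, -3.24 and -2.96 otherwise.

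With doublets kept the share of immature or transitional B-like cells had a log2 ratio of 0.0091. At Leiden resolution 2 the share of CD8 T-like cells was at 0.76, Gzma in T-like cells at 0.40, Cxcl10 in CD8 T-like cells at 0.42 and Nusap1 in regulatory T-like cells at 0.81. With each library clustered alone the shares were -1.96 for dendritic-like, 0.35 for CD8 T-like and -0.25 for marginal zone B-like cells.

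With cells thinned to 1000 UMIs the type I interferon median was 0.18 in all kept cells and 0.39 in T-like cells, the interferon gamma median 0.19 and the NF-kB median -0.22 in all kept cells. The cell cycle median in dendritic-like cells was -0.10 and the B cell activation median in monocyte-like cells 0.044. Single genes whose reported interval excluded 0 and that changed direction were H2-Eb1 (0.0086) and S100a9 (-0.028) in all kept cells, Irgm1 in dendritic-like (-0.55), Stat2 in CD4 T-like (-0.26), Tap2 in marginal zone B-like (-0.069) and Il1r2 in regulatory T-like cells (-0.40). Tnfrsf4 in dendritic-like (-1.14) and Erap1 in regulatory T-like cells (-0.083) also changed sign, from intervals that held 0. Mefv in dendritic-like cells was at -2.14. With cells weighted equally H2-Eb1 and S100a8 in all kept cells were at 0.0065 and -0.089.

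TMM factors put the inflammasome median at 0.091 and the NF-kB median at -0.20 in all kept cells, and the NF-kB median at -0.13 in B-like cells. With classes weighted to their mean shares the NF-kB median was -0.14 and the B cell activation median -0.022 in all kept cells. Without cells of over 20 Jchain or haemoglobin UMIs, the type I interferon median was 0.13 and the NF-kB median -0.18 in all kept cells.

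The mean over members was 0.16 for type I interferon and 0.082 for IL-1, IL-6 and neutrophil genes in all kept cells, -0.11 for NF-kB in B-like, 0.34 for inflammasome genes in T-like and 0.073 for B cell activation in monocyte-like cells. With no expression filter the medians were -0.12 for inflammasome genes in all kept cells, 0.19, 0.031 and 0.12 for type I interferon, inflammasome and NF-kB genes in T-like cells and 0.055 for B cell activation in monocyte-like cells. With the higher filter they were 0.13 for type I interferon and 0.17 for IL-1, IL-6 and neutrophil genes in all kept cells, 0.0017 for the latter in B-like cells, 0.46 and -0.10 for interferon gamma and NF-kB in T-like cells and 0.13 for B cell activation in monocyte-like cells.

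Some alternatives gave no value. Clustering each library alone named no plasma cell-like or macrophage-like cells in the wild-type and no gamma-delta T-like cells in the knock-in library, and resolution 2 named no immature or transitional B-like cells. The higher filter left too few members of the sex-linked list in every class compared, and of the haemoglobin, cytotoxic, naive T cell, IL-1 or B cell activation lists in some. Thinning did so for haemoglobin in T-like, sex-linked in dendritic-like and monocyte-like, naive T in monocyte-like and cytotoxic genes in marginal zone B-like cells.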

Other observations

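Tests chosen only after the result was seen were those on the mix of T cell clusters, on cell composition for short transcripts, and all 3 tests on plasma cells; the tests by regression and by rho with transcript length were chosen after the patterns, but before their own outcomes, had been seen. The cell counts and immunoglobulin segments in the last paragraph were also chosen after the data had been seen.

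Type I interferon genes were higher in knock-in T-like cells. Transcript length, GC content or expression level as the whole source is argued against by the list's residual median after regression on them, at percentile 100 among matched random lists. With every cell thinned to 1000 UMIs the median was 0.39 (0.25 to 0.53, 31 members), which argues against a heavier weight of deep cells as the source. Thinning keeps each gene's expected share of its cell, so a bias tied to depth and already in the counts cannot be excluded. The mix of T cell clusters as the whole source is argued against by medians above 0 in 5 of 5 T-like clusters of at least 100 cells per library. The counting interval lay above 0 in all but the regulatory one (-0.06 to 0.25). The medians of cluster 5 and of the regulatory cluster lay inside the random range. Mix as a part of the difference cannot be excluded, since the CD4 T-like median of 0.56 lay above those of its clusters (0.29 and 0.34). With 1 library per genotype, the genotype and a difference between individual mice or preparations both stay open, untested.

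Some very short transcripts, Rps29, Rps28, Rps21, Rps15, Rpl38, mt-Nd3 and Atp5k, were lower in the knock-in library. Transcript length was expected to run the same way across other genes, but longer transcripts were the lower ones, with a lowest rho of -0.45 over 5 classes. That is opposite to a loss that grows steadily as transcripts get shorter. It cannot exclude a loss limited to very short transcripts, because most genes behind rho were longer. The 7 genes measure 321.5 to 536 nucleotides, and the shortest length bin in B-like cells reaches 1120. Genes under 600 nucleotides had medians from -0.015 (NK-like) to 0.096 (T-like), so a loss shared by all of them was not seen. The median of the 7 genes was -0.65 in thinned B-like cells, against -0.63 otherwise, which argues against a heavier weight of deep cells as the source. Thinning keeps each gene's expected share of its cell, so a bias tied to depth and already in the counts cannot be excluded. Cell composition is argued against by medians of the 7 genes under 0 in 5 of 5 classes. Among the 80 ribosomal protein genes measured, rho with length was positive in these classes, from 0.39 to 0.47. Shorter transcripts were thus the lower ones within that set, and a loss limited to very short transcripts stays open. A step of library preparation that differed between the libraries may be a source, and no biological explanation was tested.

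Plasma cell-like cells were a larger share of the knock-in library. The cell filters and doublet calls used here are argued against by the deposited barcodes with at least 50 Jchain UMIs, 33 wild-type and 152 knock-in, a ratio of shares of 5.35 (3.65 to 8.05). How barcodes were chosen before deposit is not given, so filters applied at that step were not tested. The other clusters of large cells, with wild-type medians of 4073 to 6064 UMIs, had ratios of 0.737 (marginal zone B-like), 1.74 (CD8 T-like), 1.02 (dendritic-like) and 0.946 (monocyte-like), and of 0.988, 1.53, 0.841 and 0.773 when these same clusters were limited to cells under 5% mitochondrial UMIs, without the new clustering behind the shares given for that limit elsewhere. An equal loss of all large cells from the wild-type library as the whole source is argued against by their upper bounds, at most 2.03, under the plasma cell-like lower bounds of 3.55 and, at the 5% limit, 2.84. A loss of large cells that grew with size, or as a part of the difference, cannot be told apart from a true difference. Plasma cell-like cells were larger than the rest (wild-type median 10488 UMIs), and the upper bound of the marginal zone B-like cluster at the 5% limit was 1.17, above 1. The genotype and a difference between individual mice both stay open, untested.

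In plasma cell-like cells Ighm gave the most heavy chain constant UMIs in 24 of 35 wild-type and 117 of 159 knock-in cells, and Igha in 3 and 10. Among IgG genes it was Ighg2b in 0 and 11 cells, Ighg2c in 4 and 9, Ighg3 in 4 and 11 and Ighg1 in 0 and 1. The intervals of the Ighg2b shares overlapped (0 to 10.0% and 3.50% to 12.0%). The lambda segment Iglv1 was the most common light chain V segment, in 8 of 27 and 58 of 117 cells with at least 10 V UMIs. Of the neutrophil-like cells, 2 of 122 wild-type (1.64%) and 14 of 57 knock-in (24.6%, 14.1% to 37.8%) held over 10 UMIs of the granule genes Ngp, Camp and Ltf. Of the 20 knock-in cells with over 50 haemoglobin UMIs, 14 lay in the unnamed proliferating cluster. Jchain was at 5.09 and 19.4 CPM in B-like and 1.83 and 9.60 CPM in T-like cells, classes that should largely lack it.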
